A study of Oreochromis niloticus with 6 samples.

How the data were processed

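The material is liver RNA of male juvenile Nile tilapia (Oreochromis niloticus) of the GIFT strain, a line of this farmed fish selected for growth. The fish ate a high-fat diet (HFD, 18.5% lipid) or a normal-fat diet (NFD, 8% lipid) for 56 days, and the series holds 6 libraries, 3 per diet. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library preparation. The same protocols say that RNA from 3 samples per group was mixed, without saying whether each library is its own mixture. The p-values therefore measure the spread between libraries, which may be partly technical, or wholly so if the libraries of a diet share a mixture.

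Both deposited tables hold FPKM, the fragments of a transcript scaled to its length and to the library's sequenced fragments, per the file headers. One table lists 33245 transcripts with Ensembl transcript names, among them 426 small RNAs with Rfam names, and the other lists 19928 long non-coding RNA (lncRNA) transcripts. The submitters' processing notes name cutadapt 1.10, FastQC 0.10.1, HISAT2 2.0.4, StringTie 1.3.0 and edgeR 3.22.3, with no role or order. The genome build, the strand setting and the way a transcript was called a lncRNA are not given in the sources used here. The transcript numbers run to 78588, of which 25415 are in neither table, so reads that the authors assigned to those transcripts are not in the values analysed here. A value of 0.0001 stands for no estimate and was set to 0; 8355 transcripts of the first table have it in all 6 libraries. The sequencing depth is unknown, since low values did not come out as whole multiples of 1 read between libraries; no counting interval or floor is given. The tables give no positions. An NCBI gene table of the assembly O_niloticus_UMD_NMBU was used only to see whether consecutive gene numbers are neighbouring genes.

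Transcripts of the first table were summed per gene ID, giving 26490 gene IDs, of which 511 carry several gene names and are printed with all of them. Genes were tested when at least 3 of the 6 libraries had an FPKM of 0.5 or more, and lncRNA transcripts when at least 3 had 0.1 or more. Log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), each table alone, with diet as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. A model for counts was not used because the values are not counts. Figures were drawn with matplotlib 3.10.9.

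Gene lists, 32 in all, were fixed before the data were examined: lipid, carbohydrate and amino acid metabolism, defence and stress, cell cycle, matrix, clock, hormone axis, respiratory chain, ribosome, proteasome, early response, egg proteins and markers of 11 cell types or tissues. A symbol counted as a member when it equalled the listed name, with or without the a or b of a fish duplicate; the ribosomal, proteasome and respiratory chain lists were taken by name pattern. The 27 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Counts of members are given over all genes and adjusted over the list alone.

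The genes named in the text follow a rule also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose libraries do not overlap between diets, with a mean FPKM of at least 1 in one diet, and the 2 largest lncRNA rises and falls. It also takes up to 4 members of each list with the smallest adjusted p. The part on size named no gene and no lncRNA, since none passed; features printed outside the rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

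The lncRNA transcripts with an unadjusted p under 0.05 were paired with the gene of the same gene ID, and the share with the same sign was set against 10000 random pairings. The share of the lncRNA table in each library's summed FPKM was compared by an exact permutation test over 20 assignments. Alternatives covered pseudocounts of 0.1 and 1, filters, scaling, the variance prior, the summing of rows, the replicate number as a block and the omission of each library. A hand-written centring factor like the trimmed mean of M-values, trimming 0.3 from each end over genes with at least 1 FPKM in every library, served as the scaling alternative.

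The fits were tested on simulated data made from the real means and residual spreads, with 200 changed features. In the simulated mRNA comparison of 9204 genes, 28% of genes changed by 1 on the log2 scale were recovered, 70% of those changed by 2, 94% of those changed by 4 and 96% of those changed by 6, with 4 false calls. In the simulated lncRNA comparison of 18368 transcripts the shares were 0%, 10%, 62% and 46%, with 1 false call. All these shares apply to data with 200 changed features of these sizes. Where fewer features change, the adjustment is stricter, so the shares do not tell how many changes a real count of 0 could miss. A list of 25 genes lowered by 0.6 was the only 1 of 27 lists called. The noise was drawn independently for each gene, so this could not show false list calls from genes that vary together. In the real data the estimated correlation was 0.14 for endoplasmic reticulum stress, 0.24 for the respiratory chain and 0.29 for the proteasome, against the preset 0.01.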

Results

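Liver transcripts were measured in 6 libraries, 3 from tilapia on the high-fat diet (HFD) and 3 from tilapia on the normal-fat diet (NFD). The series asks through which pathways, and through which lncRNAs, dietary fat disturbs lipid metabolism in the liver. The summed FPKM of the mRNA table was between 141024 and 170847 per library and that of the lncRNA table between 75825 and 96354. Depth in reads is unknown. The median Pearson correlation across genes between libraries of one diet was 0.867 for mRNA and 0.574 for lncRNA, against 0.871 and 0.581 between libraries of different diets, so libraries of one diet were no more alike than libraries of different diets. Genes are not independent replicates.

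The comparison of HFD with NFD livers asks which genes respond to dietary fat. The gene with the smallest p was fabp7a (MSTRG.7331), a fatty acid-binding protein, at 0.568 ± 0.168 FPKM in HFD and 21.2 ± 11 in NFD (SD, n = 3 each), with all 3 HFD libraries below all 3 NFD libraries. Endothelial lipase, lipg (MSTRG.18938), was at 0.195 ± 0.210 and 2.02 ± 0.262 FPKM, and lipoprotein lipase, lpl (MSTRG.3362), which releases fatty acids from circulating triglyceride, at 15.8 ± 4.66 and 5.47 ± 2.30 FPKM. Over all genes these differences did not pass: 0 of 9204 genes had an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.235. At an unadjusted p under 0.05 there were 554 genes, 246 higher and 308 lower in HFD, where 460 would be expected by chance. The other splits of the 6 libraries into 3 and 3 gave between 289 and 824 such genes, so 554 lies within their range. The diets did not overlap for 1070 genes, 11.6% of those tested, where chance gives 10%. Without NFD replicate 2 the count past the threshold was 4, and 345 of 538 genes with an unadjusted p under 0.05 were higher in HFD.

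Among lipoprotein and lipid transport genes, single members were lower in HFD. Of 24 tested members, 0 passed over all genes and 3 fell when adjusted over the list alone. Among them were fabp7a (log2 fold change -4.22 ± 0.39 SE) and lipg (-1.89 ± 0.26). Fabp7a varied 20-fold or more between libraries, but that variation followed diet, so leaving out such genes also takes out its diet difference. Lpl, higher in HFD, had an adjusted p over the list alone of 0.0558 in limma. The list as a whole did not pass camera (adjusted p = 0.178; adjusted p = 0.597 with an estimated correlation), with 11 members higher and 13 lower in HFD. Its median log2 fold change was -0.10 and its mean -0.31; the mean was -0.15 without genes varying 20-fold, -0.19 without NFD replicate 1 and -0.51 without HFD replicate 2. It was the list that passed fry in either direction (adjusted p = 5.55e-06), an alternative chosen after the data were seen. Fry in one direction gave an adjusted p of 0.359. No result of fry in either direction without fabp7a is given, so it does not show how many members carry it. With camera's preset correlation the list's adjusted p ranged from 0.0188, without HFD replicate 2 (0.709 with an estimated correlation), to 0.776, without NFD replicate 1.

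Genes of fat synthesis, oxidation and storage did not pass as lists or singly with all libraries. In the list of fatty acid and triglyceride synthesis (19 tested, camera adjusted p = 0.596), acetyl-CoA carboxylase ACACA (MSTRG.18267) was at 0.953 ± 0.362 FPKM in HFD and 2.33 ± 0.689 in NFD. The elongase elovl5 (MSTRG.5055) was at 13.4 ± 1.15 and 23.3 ± 5.62 FPKM, and the desaturase fads2 (MSTRG.4351) at 20.05 ± 22.3 and 96.7 ± 59.0 FPKM with overlapping libraries. Fads2 varied 20-fold or more between libraries. The fourth named member was agpat2 (MSTRG.17087), at 2.13 ± 0.346 and 3.16 ± 0.796 FPKM. In fatty acid oxidation and ketogenesis (25 tested, adjusted p = 0.843), the peroxisomal enzyme ehhadh (MSTRG.13631) was at 1.13 ± 0.701 and 5.52 ± 1.99 FPKM. In lipid droplets and lipolysis (7 tested, adjusted p = 0.577), the triglyceride lipase pnpla2 (MSTRG.4355) was at 14.2 ± 2.87 FPKM in HFD and 6.23 ± 2.31 in NFD. Without HFD replicate 2 and NFD replicate 3 together, an alternative chosen after the data were seen, that list passed camera (adjusted p = 0.0380, or 0.771 with an estimated correlation). Its mean was then 0.53 over 6 tested members against 0.14 over 7. The member fitm2 (MSTRG.30121), lower in HFD with all libraries, missed the filter there. With the preset correlation the list's adjusted p reached 0.877, without HFD replicate 1. In each of ACACA, elovl5, ehhadh and pnpla2 the libraries of the diets did not overlap.

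Sterol and bile acid genes gave 1 member past the list-wise adjustment. The sterol exporter subunit abcg5 (MSTRG.1349) fell when adjusted over the list alone (limma, adjusted p = 0.0228), from 14.2 ± 1.41 FPKM in NFD to 6.23 ± 1.41 in HFD, a log2 fold change of -1.14 ± 0.22 SE. Its partner abcg8 (MSTRG.1350) was at 2.02 ± 1.08 FPKM in HFD and 4.02 ± 1.24 in NFD, and the bile salt export pump abcb11b (MSTRG.4720) at 5.92 ± 0.177 and 9.10 ± 1.88. The gene ID of the oxysterol hydroxylase cyp7b1 (MSTRG.32870), which also carries ENSONIG00000014068 and ENSONIG00000023515, was at 6.41 ± 4.77 FPKM in HFD and 1.03 ± 0.257 in NFD, with overlapping libraries. The 13 tested genes of bile acid synthesis and transport did not pass as a list (camera adjusted p = 0.687), and their median of 0.03 and mean of 0.07 lay above 0 while camera's direction was down. Their signs rest on single libraries: without HFD replicate 1 the median was -0.26 and the mean -0.0024, without HFD replicate 2 both were also below 0, and without NFD replicate 2 or 3 the median was. Of 18 tested genes of cholesterol synthesis and uptake, 13 were higher and 5 lower in HFD (adjusted p = 0.577); mvk (MSTRG.20014), mevalonate kinase, was at 4.31 ± 1.21 and 2.58 ± 0.194 FPKM. The direction of the cholesterol list rests on HFD replicate 2: without it 14 of 17 tested members were lower and the mean turned from 0.21 to -0.23 (adjusted p = 0.0214; adjusted p = 0.709 with an estimated correlation). With the preset correlation its adjusted p reached 0.712, without NFD replicate 2.

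Genes of glucose release and amino acid breakdown included single members that were higher in HFD, but neither list passed. Glucose-6-phosphatase g6pca.1 (MSTRG.15583), the last step of glucose release, was at 24.9 ± 3.76 FPKM in HFD and 10.8 ± 3.16 in NFD, and fructose-bisphosphatase fbp1b (MSTRG.17063) at 193 ± 42.6 and 113 ± 17.4. Phosphoglycerate kinase pgk1 (MSTRG.19714) was at 63.6 ± 2.71 and 42.8 ± 5.55 FPKM. Of 27 tested genes of glycolysis and gluconeogenesis, 15 were higher and 12 lower (camera adjusted p = 0.265). Of 29 genes of amino acid catabolism and the urea cycle, 21 were higher and 8 lower (adjusted p = 0.177), with proline dehydrogenase prodha (MSTRG.23541), which varied 20-fold or more between libraries, at 6.19 ± 4.31 and 1.17 ± 0.762 FPKM. Haao (MSTRG.20906), of tryptophan breakdown, was at 48.0 ± 2.997 FPKM in HFD and 72.5 ± 4.03 in NFD. The amino acid list passed without HFD replicate 1 (adjusted p = 0.0226; adjusted p = 0.874 with an estimated correlation) and without NFD replicate 1 (adjusted p = 0.0369; adjusted p = 0.708 with an estimated correlation). With all libraries it had an adjusted p = 0.597 with an estimated correlation.

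The list of endoplasmic reticulum (ER) stress genes was lower in HFD, and was 1 of the 3 that passed camera. Of 25 tested members, 16 were lower and 9 higher, with a median log2 fold change of -0.39 and a mean of -0.60 (adjusted p = 0.00221 with the preset correlation, adjusted p = 0.597 with an estimated correlation). Over all genes 0 members passed, and 4 fell when adjusted over the list alone. The chaperone hsp90b1 (MSTRG.8630) was at 16.0 ± 8.43 FPKM in HFD and 84.0 ± 55.8 in NFD, the disulfide isomerase pdia4 (MSTRG.8116) at 16.3 ± 8.01 and 62.9 ± 24.9. The isomerase pdia6 (MSTRG.33077) was at 1.37 ± 0.449 and 4.13 ± 1.28 FPKM, and the co-chaperone dnajc3a (MSTRG.13507) at 2.99 ± 0.674 and 8.61 ± 2.43. These 4 are chaperones and folding enzymes. Among the 9 higher members, chosen after their values were seen, atf4a was at 26.4 ± 2.06 FPKM in HFD and 19.9 ± 3.95 in NFD, and chac1 at 34.1 ± 1.64 and 30.4 ± 10.2.

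The proteasome and the mitochondrial respiratory chain were the other lists to pass camera. Of 41 tested proteasome genes, 36 were lower and 5 higher in HFD, with a median log2 fold change of -0.23 (adjusted p = 0.00221; adjusted p = 0.895 with an estimated correlation). Psmd8 (MSTRG.35755), of the regulatory particle, was at 6.41 ± 0.727 and 9.36 ± 1.71 FPKM, and psma1 (MSTRG.26523), of the core, at 2.62 ± 0.230 and 3.48 ± 0.303. The name pattern also took psmc3ip, which is no proteasome subunit. Of 64 genes in the respiratory chain list, 48 were lower and 16 higher, with a median of -0.13 (adjusted p = 0.0109, or 0.895 with an estimated correlation). Its name pattern also took the assembly factor sdhaf4 and gene IDs with several names. One of these, cox6a1/pla2g1b, also counted as an exocrine pancreas marker. Atp5l (MSTRG.32580), an ATP synthase subunit, was at 6.42 ± 1.502 and 11.5 ± 1.77 FPKM. In both lists 0 members passed, over all genes or adjusted over the list alone. Without NFD replicate 2 the proteasome list had 27 of 40 members lower, a median of -0.12 and an adjusted p of 0.0852, and without NFD replicate 3 the respiratory chain list had 37 of 63 lower, a median of -0.04 and an adjusted p of 0.192. With the preset correlation the adjusted p ranged from 6.29e-05 to 0.0852 for the proteasome and from 0.00135 to 0.251 for the respiratory chain.

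**Figure D1:**
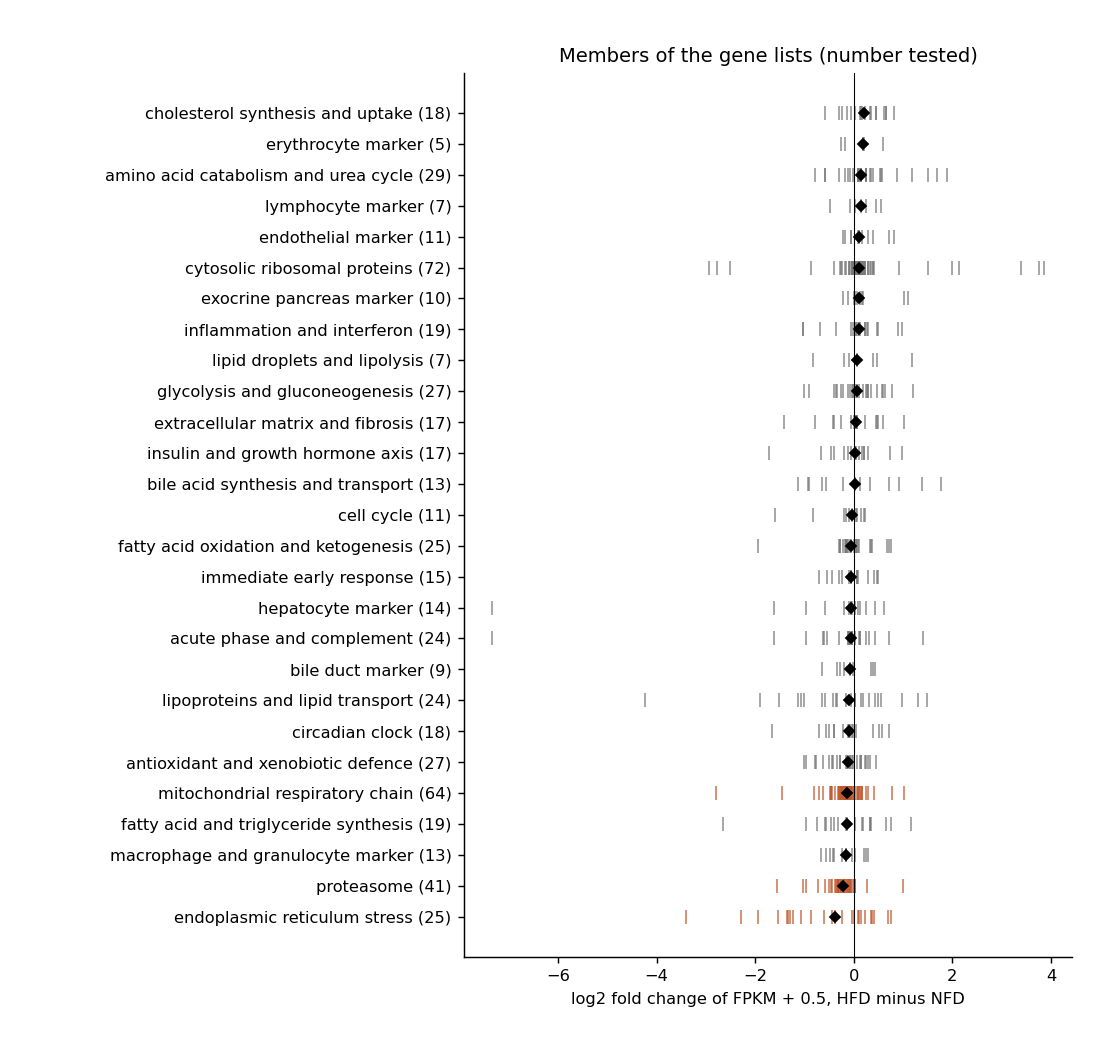
Log2 fold change (HFD minus NFD, of FPKM + 0.5) of each tested member of the 27 tested gene lists, 1 tick per gene, with the list's median as a diamond and the number tested in brackets; lists past an adjusted p of 0.05 with the preset correlation are in orange. The ER list has the lowest median, -0.39, and most lists centre near 0.

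**Figure D2:**
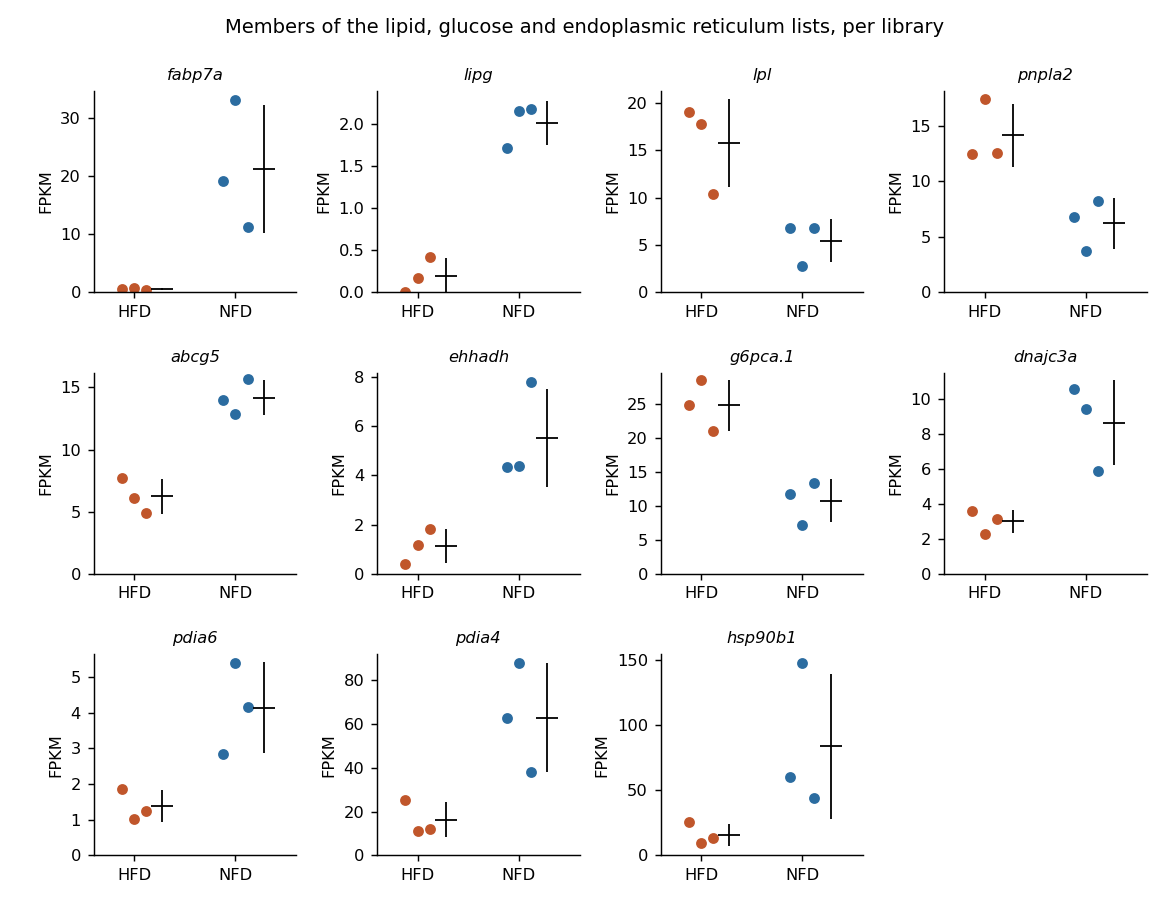
FPKM of 11 genes named from the gene lists, 1 point per library (3 HFD, 3 NFD), with the mean and SD of each diet in black and axes starting at 0. The diets do not overlap in any of the 11 genes. Lpl, pnpla2 and g6pca.1 are higher in HFD and the other 8 lower. Named members whose diets overlap, such as fads2, agpat2 and abcg8, are not shown. Among all tested genes, 11.6% do not overlap, where chance gives 10%.

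Defence, inflammation and growth lists did not pass. Of 27 antioxidant and xenobiotic genes, 18 were lower in HFD (camera adjusted p = 0.177), among them cyp1a (MSTRG.323, a gene ID that also carries ENSONIG00000002932), the main dioxin-induced oxidase, at 12.98 ± 3.35 FPKM in HFD and 26.0 ± 0.812 in NFD. That list passed without NFD replicate 3 (adjusted p = 0.0449; adjusted p = 0.776 with an estimated correlation), within a range from 0.0206 to 0.357 over the alternatives with the preset correlation. In inflammation and interferon (19 tested, adjusted p = 0.577), nfkb2 (MSTRG.31027) was at 2.18 ± 0.156 and 0.996 ± 0.540 FPKM while nfkb1 (MSTRG.14101) was at 0.230 ± 0.200 and 1.00 ± 0.554. Of 24 acute phase and complement genes, 15 were lower (adjusted p = 0.744). Adjusted p was 0.577 for the cell cycle (11 tested), 0.928 for extracellular matrix and fibrosis (17), 0.572 for the circadian clock (18), 0.843 for the insulin and growth hormone axis (17) and 0.941 for the immediate early response (15). In the hormone axis the mean was -0.05 while the median, 0.03, and camera's direction were up, and in the early response the median and mean were negative while camera's direction was up. Of 72 genes in the list of cytosolic ribosomal proteins, 53 were higher and 19 lower (adjusted p = 0.362; 0.0188 without HFD replicate 2, where adjusted p = 0.713 with an estimated correlation, and 0.991 without HFD replicate 3). Without NFD replicate 1, 43 of 71 were lower. The name pattern also took 4 kinases of the rps6k family. RPL7A (MSTRG.17121) fell when adjusted over the list alone (limma, adjusted p = 0.0494), from 875 ± 153 FPKM in NFD to 166 ± 83.2 in HFD. In the small list of egg proteins and oestrogen receptors, 4 members were tested and none passed.

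Transcripts of some digestive enzymes made by the exocrine pancreas were abundant in every library and varied within both diets. The trypsinogen prss1 (MSTRG.37121) ranged from 2306 to 10472 FPKM and the elastase ela2 (MSTRG.9934) from 827 to 3257, both chosen after their values were seen. HFD replicate 3 and NFD replicate 1 held the highest values of prss1. The 10 tested exocrine pancreas markers had a median log2 fold change of 0.10 (camera adjusted p = 0.687). Without NFD replicate 1 all 9 tested markers were higher in HFD (adjusted p = 0.0204; adjusted p = 0.896 with an estimated correlation), while without NFD replicate 3 all 10 were lower (adjusted p = 0.149) and without HFD replicate 3, 7 of 9 were lower. With the preset correlation the adjusted p reached 0.755. Adjusted p was 0.687 for hepatocyte markers (14 tested), 0.687 for erythrocyte (5), 0.431 for macrophage and granulocyte (13), 0.830 for lymphocyte (7), 0.577 for endothelial (11) and 0.687 for bile duct markers (9). Too few members were tested for the endocrine pancreas (1), skeletal muscle (1), adipocyte (2) and intestine (4) lists. Of the 2 adipocyte markers tested, lpl rose when adjusted over the list alone (limma, adjusted p = 0.0186), an adjustment over only 2 genes. Over all genes its adjusted p in limma was 0.708. The other marker, slc7a10a (MSTRG.373), was at 0.627 ± 0.133 FPKM in HFD and 0.525 ± 0.0701 in NFD, with overlapping libraries.

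**Figure D3:**
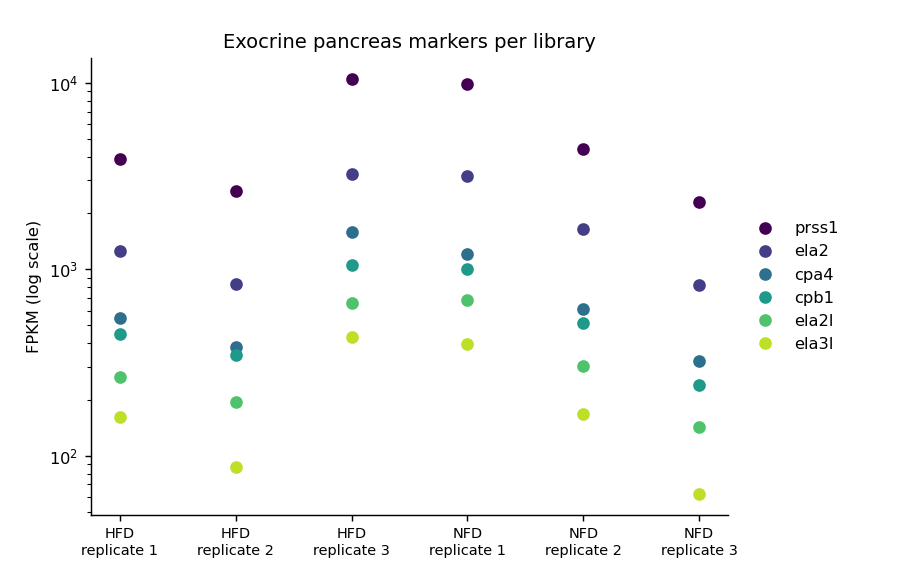
FPKM (log scale) of 6 exocrine pancreas markers in each of the 6 libraries, 1 colour per gene. The genes move together and are highest in HFD replicate 3 and NFD replicate 1, for example prss1 at 10472 and 9855.

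The lncRNA comparison asks which non-coding transcripts respond to dietary fat. None passed: 0 of 18368 tested lncRNA transcripts had an adjusted p under 0.05 in limma. The smallest adjusted p was 0.0546, shared by MSTRG.17221.1, MSTRG.18275.1 and MSTRG.38085.2, which were chosen after their values were seen. MSTRG.17221.1 was at 6.76 ± 0.810 FPKM in HFD and 0.214 ± 0.101 in NFD (SD, n = 3 each), a log2 fold change of 3.35 ± 0.32 SE. MSTRG.18275.1 was listed at 0 in all 3 HFD libraries and at 3.91, 3.92 and 4.43 FPKM in the NFD libraries. MSTRG.38085.2 was listed at 0 in all 3 NFD libraries and at 34.0, 8.89 and 12.9 FPKM in HFD. At an unadjusted p under 0.05 there were 778 transcripts where 918 would be expected by chance, 523 higher (67.2%) and 255 lower in HFD. Without NFD replicate 2 there were 1170 where 896 would be expected. The share that was higher became 57.5% with the trimmed-mean centring and 52.9% with quantile normalization. Diets did not overlap for 9.81% of transcripts, where chance gives 10%.

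The files name no distances, and lncRNAs were set beside the gene that carries the same gene ID. Of 24 lncRNA transcripts with an unadjusted p under 0.05 and a tested gene of the same ID, 14 (58.3%) had the same sign as that gene, against 50.1% over random pairings (permutation p = 0.685, two-sided). Without HFD replicate 3 the share was 78.9% of 19 pairs (permutation p = 0.0234), so the call depends on this library. The random pairings treated the pairs as independent, although several lncRNAs can share a gene ID.

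The lncRNA table made up 38.1% ± 3.05 of the summed FPKM in HFD and 34.7% ± 1.56 in NFD (SD, n = 3 each). The difference of 3.36 percentage points did not pass (exact permutation test, two-sided p = 0.3, smallest possible p 0.1). A single transcript, MSTRG.5224.1, chosen after its values were seen, took 25.3% to 37.4% of the lncRNA total in each library.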

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

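The alternatives without HFD replicate 2 and NFD replicate 3 together, with rows summed per gene name, without strongly varying genes, with fry in either direction and without Rfam-named rows were chosen after the data were seen. For mRNA the count of 0 was kept under both pseudocounts, both filters, both scalings, both variance priors, per transcript and per gene name. It became 203 with an unadjusted p and an absolute log2 fold change of 1 or more, and ranged from 0 to 4 when 1 library was left out: without NFD replicate 2, fgb, nfil3-6, f11r.1/ubash3ba and ENSONIG00000026835 passed. For lncRNA the count of 0 became 1 with a pseudocount of 0.1, 2 with a filter at 1 FPKM, 3 with a robust prior and 644 with the unadjusted rule, and ranged from 0 to 3 with 1 library left out (3 without HFD replicate 2, 2 without NFD replicate 2, 1 each without HFD replicate 3 and NFD replicate 1). The number of lists past the threshold, 3, became 0 with an estimated correlation, 0 with fry, 1 with fry in either direction and 5 without the pair of libraries, and ranged from 2 (without NFD replicate 2) to 6 (without HFD replicate 2), with 5 without NFD replicate 1. The mean log2 fold changes of the ER (-0.60), respiratory chain (-0.17) and proteasome (-0.26) lists did not pass with an estimated correlation or fry. With 1 library left out they ranged from -0.29 to -0.11 for the respiratory chain, lost without NFD replicate 3, from -0.41 to -0.18 for the proteasome, lost without NFD replicate 2, and from -0.74 to -0.43 for the ER list, which passed each time. The respiratory chain, at -0.086, was also lost without the pair of libraries. The cause was not tested for any of these. Of 331 other values of the 24 lists that did not pass, 30 had the other sign and 10 passed; of 117 named genes, 12 changed sign in some setting, and fgb alone passed in 1. The same-sign share of lncRNAs and their genes ranged from 40.9% to 78.9%, and the difference in lncRNA share from 2.32 to 5.11 points. Replicate numbers do not pair the samples: the deviations of same-numbered HFD and NFD libraries from their diet's mean correlated at -0.0052, -0.201 and -0.106 for mRNA and at -0.0023, -0.304 and -0.175 for lncRNA. With the replicate block, 0 mRNAs, 0 lncRNAs and 3 lists passed. Distances of 10 kb and 1 Mb were not run because the files give no positions. Unknown depth leaves the precision of low values open.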

Other observations

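Besides the list members, single genes differed at an unadjusted p under 0.01, with libraries that did not overlap between diets. Those named were chosen after their values were seen, not by size, and none passed the adjusted threshold. Among lower genes outside the lists, fam199x (log2 fold change -1.80), tead1b (-1.63) and slc22a5 (-1.60) fell more than any named here. The genes named therefore give no independent support to the ER list. Lower in HFD, the calreticulin calr3b (MSTRG.15231) was at 27.1 ± 11.6 FPKM in HFD and 80.7 ± 27.6 in NFD (SD, n = 3 each), the disulfide isomerase txndc5 (MSTRG.8173) at 9.99 ± 1.73 and 21.0 ± 4.61, and the glucosidase subunit prkcsh (MSTRG.6253) at 2.36 ± 0.215 and 6.22 ± 1.80. The signal peptide peptidase hm13 (MSTRG.11334) was at 11.1 ± 1.68 and 20.5 ± 1.64 FPKM, the cargo receptor tmed3 (MSTRG.221) at 3.04 ± 1.48 and 8.78 ± 2.65, and mydgf (MSTRG.3260) at 14.6 ± 3.07 and 30.3 ± 6.59. The protease inhibitor SERPINA4 (MSTRG.4618) was at 29.4 ± 11.4 and 87.2 ± 23.0 FPKM. On the other side, the mitochondrial carrier slc25a48 (MSTRG.14042), which varied 20-fold or more between libraries, was at 19.6 ± 10.2 FPKM in HFD and 2.26 ± 1.49 in NFD, the linker histone h1f0 (MSTRG.1890) at 36.3 ± 7.31 and 16.9 ± 0.465, and the peroxisomal import receptor pex5 (MSTRG.18470) at 5.52 ± 1.54 and 2.25 ± 0.616. A further count took genes with a symbol, a mean FPKM of at least 1 in one diet and libraries that did not overlap. At an unadjusted p under 0.01, 53 such genes were lower and 23 higher in HFD, list members such as hsp90b1 and pdia4 included. No number expected by chance was worked out for this rule, so the counts do not show an excess.

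Small structured RNAs made up between 19.1% and 29.7% of the summed FPKM of the mRNA table. The highest, chosen after their values were seen, were 7SK (RF00100), at 9427 ± 850 FPKM in HFD and 8179 ± 1607 in NFD, and the spliceosomal U2 RNA (RF00004), at 6973 ± 2895 and 9855 ± 4973.

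The tests of members that switch on and off in the ER list, of both explanations for the pancreas markers, of other splits for genes and lncRNAs, and of neighbouring numbers without single libraries were chosen after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 10 gave at least the real count of 0 mRNAs and 10 the real count of 0 lncRNAs, with up to 11 and 42 in the other splits; any split gives at least 0, so these counts of splits test nothing. For lists, 5 of the 10 splits gave 3 or more, and the highest other count was 5. At an unadjusted p under 0.05 the real split gave 554 genes and 778 lncRNAs. The other splits gave between 289 and 824 genes and between 522 and 2342 lncRNAs. The split of HFD replicates 1 and 3 with NFD replicate 2 against the rest gave the 11 genes and the 42 lncRNAs, which points to a structure of the samples that does not follow diet.

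The lower ER list in HFD could reflect diet, the amount of pancreas, or genes whose values switch between libraries. The mean log2 difference of its 25 members was -0.60 (95% interval -1.23 to 0.03, 4 residual df). With the pancreas score as a covariate it was -0.60 (-1.44 to 0.24, 3 residual df), so the estimate did not move. Diet held 1.69% of the variance of that score, so the covariate had little diet difference to remove. The estimate thus gave no sign of this explanation, but the intervals with and without the covariate include 0 and do not settle it. Without the 1 member that varied 20-fold or more, hspa5, the difference was -0.48 (-0.93 to -0.03), which argues against such genes as the whole cause. Diet stays open as an explanation, and was not separated from chance.

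Among 877 genes with a symbol that reached 10 FPKM, 74 varied 20-fold or more between libraries. Fgb, which encodes a fibrinogen chain, was at 3857 and 3101 FPKM in NFD replicates 1 and 3 and between 0.835 and 1.18 in the other 4 libraries, and rps15a, chosen after its values were seen, was at 4.35 FPKM in NFD replicate 1 and between 267.6 and 364 elsewhere. A candidate explanation is that reads go to assembled transcripts listed in neither table: an unlisted transcript number stood beside or between those of 89.2% of the varying and 73.5% of the other genes, an odds ratio of 2.90 at a like level (95% interval 1.37 to 6.14). Only the level was matched, and a gene with a longer run of transcript numbers has more chances of an unlisted one. The odds ratio therefore does not tell this explanation from the number of transcripts per gene. For fgb itself no number beside it was unlisted. Diet split 3 of the 74 genes: fabp7a, slc25a48 and prodha. That is 4.05% (exact 95% interval 0.844 to 11.4), which argues against diet as the main source.

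The exocrine pancreas markers varied together, with a median pairwise correlation of 0.854 over the libraries, against 0.023 for random lists matched on level, of which 0 of 10000 were as high. This is consistent with differing amounts of pancreatic tissue in the dissected organ, as a hypothesis. Diet held 1.69% of the variance of the marker score, which argues against diet as the main source, since prss1 ranged from 2618 to 10472 FPKM within HFD alone. The direction turned with the library left out, with a mean log2 difference of 0.87 without NFD replicate 1 and -0.47 without NFD replicate 3.

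Neighbouring transcripts may move together. Gene numbers follow position: 94.9% of 6154 consecutive gene pairs at most 3 numbers apart lie on one chromosome of the reference assembly. Of the 778 lncRNAs with an unadjusted p under 0.05, 403 had a numbered tested gene of another gene ID at most 3 numbers away. Of these 403, 56.3% had the sign of the nearest such gene, against 50.6% in random pairings (permutation p = 0.0190). The random pairings treated the pairs as independent, although several lncRNAs can share a nearest gene, so the p may be too small. The call depends on 2 libraries: the share was 47.7% without HFD replicate 2 (permutation p = 0.135) and 50.1% without NFD replicate 1 (permutation p = 0.627), while without each of the other 4 libraries it was between 57.1% and 59.2%, with a permutation p of at most 0.0140.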
